A study of Bombina orientalis with 18 samples.

How the data were processed

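Polyadenylated RNA of whole brains from Bombina orientalis was measured by sequencing in 18 libraries, 3 for each of 6 groups, per the labels. The groups were short training (12 trials) and long training (36 trials), each at 2 h and 24 h, and libraries of an earlier experiment at 2 h and 24 h. Per the submitters' processing notes, Bowtie2, RSEM and DESeq2 were used; versions and settings are not given in the sources used here. Contigs carried Trinity names, per the file headers, and no genome build applied.

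The deposited data comprised 4 gene tables, 2 isoform tables and a Trinotate annotation, per the file headers. The signal values were the authors' DESeq2 base means, that is, normalized counts averaged over the libraries of an arm, per the file headers. The log2 values were the authors' deposited log2 fold changes of the first over the second arm, checked here against the arm means. The standard errors of those fold changes were taken from the authors' deposited tables for long against short training. The score values were the authors' Wald statistics, the log2 fold change over its standard error, per the file headers. Each p-value and adjusted p was the authors' deposited DESeq2 value, and contigs with no p carried an adjusted p of 1 and were left out. No values per library were analysed here, so no count model was refitted and the precision given by depth could not be stated. The replicates may be technical, since the labels do not say whether each came from its own animal.

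The first arm of the other pair of tables was headed Ext and the second Aqu, per the file headers, and they are called the extinction and acquisition arms here. The labels attach these tables to the short-trained and earlier-experiment libraries without saying which arm is which. Both isoform tables had column headings that named the other comparison than the table's title did, and the headings were followed. The column headed long against short training at 24 h stays in doubt, as set out below. The annotation held 1048575 lines, the limit of a spreadsheet, and reached Trinity component 384098, whereas the gene tables reached 734118, so only 49.0 to 49.4% of the contigs tabled had an annotation entry.

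A contig passed at an adjusted p under 0.05 with no fold minimum. Differences of effect between the times were tested as z, the difference of the log2 fold changes over the root of the summed squared standard errors, with Benjamini-Hochberg adjustment. For the extinction and acquisition arms, standard errors were derived here from the fold change and its p. In all, 25 fixed lists of cell-type, synaptic, neuropeptide and metabolic genes were written beforehand. Each list took the contig of highest mean per symbol at an E-value of 1e-05 or less, and its median was compared with 10000 random lists matched over 10 deciles of mean level and on the source of the name. The smallest permutation p this allowed was 1e-04, and lists with fewer than 5 members were not tested. Calls in common were set against independent lists by Fisher's exact test. From the standard errors, 100 simulated draws gave the correlation that a shared arm would produce if each arm carried an equal share of the variance. Gene Ontology terms of 5 to 300 proteins and non-vertebrate hits were tested by Fisher's exact test. Component sums had 0.5 added before logs were taken.

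Genes were named by a rule: among contigs past the threshold with a metazoan hit at an E-value of 1e-10 or less and a base mean of 10 or more, the 8 largest changes in each direction, the passing members of the fixed lists up to 15, and FOS, EGR1, ARC, NPAS4 and BDNF always. A few genes that this rule names are not reported here. The thresholds, comparisons, lists, naming rule and most alternatives were chosen before the data were examined. Chosen after were the restriction to contigs with both arms above 0, names taken from the isoform tables for 7562 contigs, the minimum list size, the Gene Ontology tests, list tests across time, the genes named by those additions and proteolipid protein, which lies outside the list. Most myelin, glial and synaptic names at 24 h came from the isoform tables. These list only isoforms with an adjusted p up to about 0.25, so such names depend in part on the change tested. The lists were therefore tested again, also after the data were seen, with random contigs matched on listing in the columns of the same time, and with names only from the columns of the other time.

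Alternatives changed the threshold, fold minimum, mean level, annotation, adjustment, contig choice and list statistic. The code was tested on simulated data: of 200 list tests with no change, 6% fell under p 0.05 for long against short training at 2 h, and a myelin list lowered by 0.5 was found in 10 of 10 runs. Contigs were drawn independently there, so the 6% does not cover genes of a list that vary together. Genes are not independent replicates, and the permutation compares a list with other genes in these libraries, not conditions. For the difference between times over 100705 contigs, 4%, 20% and 45.5% of contigs changed by 1, 2 and 4 log2 units were recovered. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.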

Results

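Whole brains of the fire-bellied toad Bombina orientalis, an anuran amphibian, were taken after a learning task and their polyadenylated RNA was sequenced. The series held 18 libraries in 6 groups of 3. Toads trained for 12 trials (short training) or 36 trials (long training) were sampled 2 h or 24 h after training. A further 3 libraries at 2 h and 3 at 24 h came from an earlier experiment of the submitters. Expression was reported per contig of a transcriptome assembled without a reference genome, so gene names below are those of the closest Swiss-Prot protein and no chromosome position applies. The deposited tables gave means per arm and no values per library, so the depth of each library is unknown. The replicates may be technical, and p-values then measure the spread between libraries alone.

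Long against short training asked how the number of trials showed in brain expression at each time. At 2 h, the iron carrier serotransferrin stood higher after long training in the authors' deposited table, with 7244 against 4420 normalized counts for serotransferrin-B (contig TRINITY_DN359222_c3_g1). Its log2 fold change was 0.71 with SE 0.10 (DESeq2 adjusted p 3.0e-10) in the authors' deposited table. A separate transferrin contig had 4067 against 2653 in the authors' deposited table (log2 fold change 0.62, adjusted p 0.0010). Glutaredoxin-2, a redox enzyme of mitochondria, was listed in the authors' deposited table at 201 against 3.48, a log2 fold change of 5.81 with SE 0.75 and adjusted p 3.4e-11. A contig of the sodium pump subunit AT1A3 rose by 2.18 on the log2 scale in the authors' deposited table, from 73.7 to 334 (adjusted p 2.3e-06). Lower after long training were the interferon-induced IFIT5 (7.79 against 50.3, log2 fold change -2.70 in the authors' deposited table). So was an MHC class I chain, which presents antigen (151 against 275, log2 fold change -0.87, adjusted p 0.0048 in the authors' deposited table).

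Further contigs were higher after long training at 2 h in the authors' deposited table: the ATP-gated channel P2RX7 (105 against 47.4, log2 fold change 1.15), the collagenase MMP13 (229 against 66.1, 1.80), the glyoxalase GLO2 (221 against 103, 1.10) and the RNA polymerase I subunit RPA49 (253 against 76.5, 1.72). The authors' deposited table also had AAMDC at 488 against 134 (1.87) and KLDC4 at 209 against 59.2 (1.82). The transcription factor ITF2 was lower, with 2.18 against 49.4 in the authors' deposited table (log2 fold change -4.49, adjusted p 0.035). Several called contigs were listed at 0 in 1 arm of the authors' deposited table. A contig of monoamine oxidase A, which breaks down monoamine transmitters, had a mean of 32.5 after long training and was listed at 0 after short training in the authors' deposited table (adjusted p 8.2e-04). At 24 h the same contig had 33.5 against 57.6. At 2 h, 1 of 6 members of the monoamine and acetylcholine list was higher, but 0 of 12 once names from the isoform tables were added. The zinc finger contigs Z585B and ZN691 had means of 60.4 and 21.8 after long training and were listed at 0 after short training in the authors' deposited table. In the other direction, the authors' deposited table listed at 0 after long training the tubulin contig TBA1B (1939 after short training), the ciliary DRC8 (211), the splicing factor TXN4B (178) and the nucleolar UTP11 (68.9). Means of 50.4 for FHR2, 42.9 for ZO71, 42.6 for SRFB1 and 41.2 for ZNF84 after short training likewise faced a listed 0 in the authors' deposited table.

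Across the authors' deposited table at 2 h, 1929 of 141185 contigs passed an adjusted p of 0.05 by DESeq2, 887 higher and 1042 lower after long training. Of these, 1606 had 1 arm listed at 0, and 323 had both arms above 0 (145 higher, 178 lower). As groups, cytosolic ribosomal proteins lay higher after long training, with a median log2 fold change of 0.20 over 45 members of the authors' deposited table (adjusted permutation p 0.0045 against random lists of matched level). The nuclear-encoded subunits of oxidative phosphorylation had a median of 0.18 over 49 members in the authors' deposited table (adjusted permutation p 0.012). Voltage-gated channels had a median of -0.22 over 11 members (adjusted permutation p 0.044). They no longer passed with a mean over transcripts (-0.01), an E-value of 1e-20 or less (-0.12), isoform-table names (-0.08) or the Wald statistic (median -0.23). No member of these 3 lists passed singly in the authors' deposited table, and adjusted over the list alone the count was 0 in each. At an unadjusted p under 0.05 by DESeq2 there was 1 ribosomal member, 1 of oxidative phosphorylation and 0 channels. Of the 15 lists large enough to test, 3 passed, and contigs with a protein hit had a median log2 fold change of 0.06 as a class.

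At 24 h, galanin, a neuropeptide of hypothalamic and brainstem neurons, was higher after long training, with 489.6 against 231.8 in the authors' deposited table (contig TRINITY_DN381228_c0_g2, log2 fold change 1.08 with SE 0.23, DESeq2 adjusted p 7.4e-04). The adhesion molecule NCAM2 fell by 0.50 on the log2 scale in the authors' deposited table (681 against 961, adjusted p 2.4e-04). A gamma protocadherin, PCDGG, fell by 1.02 (84.3 against 171) in the authors' deposited table. Dynamin-1, which pinches off synaptic vesicles, was higher at 458 against 320 in the authors' deposited table (log2 fold change 0.52, adjusted p 0.013). The MHC class I contig that was lower at 2 h was also lower at 24 h, with 57.8 against 212.7 in the authors' deposited table (log2 fold change -1.88, adjusted p 0.024).

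Also higher at 24 h in the authors' deposited table were complement factor H, CFAH (465 against 94.2, log2 fold change 2.30), the elongation factor TCEA1 (948 against 589, 0.69) and TM59L (1964 against 1557, 0.33). Transcobalamin-2, which carries vitamin B12, had a mean of 332 after long training and was listed at 0 after short training in the authors' deposited table (adjusted p 2.8e-14). Similar listings at 0 after short training were found in the authors' deposited table for PHP14 (210.1 after long training), ZN517 (61.9) and ZN271 (42.4). Lower contigs of the authors' deposited table included skeletal muscle actin ACTS (403 against 867, log2 fold change -1.11), annexin A5 (641 against 999.9, -0.64), FGFP3 (197 against 312, -0.67) and the autophagy protein WIPI4 (66.4 against 183, -1.46). The poly(A)-binding protein EPAB was at 5.35 against 50.1 and PLPL7 at 156 against 242 in the authors' deposited table (log2 fold changes -3.22 and -0.63). The authors' deposited table listed at 0 after long training the contigs S35U4 (mean 72.0 after short training), ZN300 (50.1), the protocadherin PCDGK (37.3), ZG8 (37.2), ZN213 (36.1), ZG26 (33.4), PRDM9 (32.3) and ZG49 (27.9). A COX3 contig of the mitochondrial genome had 96163 after long training and 0.70 after short training in the authors' deposited table, while another COX3 contig of the same Trinity component had 78525 against 210565 and did not pass.

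At 24 h, 2000 of 140241 contigs passed in the authors' deposited table by DESeq2, 1013 higher and 987 lower after long training, and 423 of them had both arms above 0 (236 higher, 187 lower). The cytosolic ribosomal proteins had a median of -0.15 over 42 members of the authors' deposited table (adjusted permutation p 0.027), the single list of 16 to pass. No ribosomal member passed singly by DESeq2, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The list no longer passed with a mean over transcripts (-0.13) or with the Wald statistic (-0.68). Among 15 neuropeptides of the authors' deposited table, galanin alone rose (1 adjusted over the list alone). Contig names were also added from the isoform tables, a step chosen after the data were seen. Those tables list only isoforms with an adjusted p up to about 0.25, so membership under these wider names depends in part on the changes tested. The oligodendrocyte and myelin list then had a median of -0.30 over 11 members (adjusted permutation p 0.0070), with no member past the threshold singly, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 by DESeq2. With names added only from the 2 h columns, which share no library with 24 h, it had -0.27 over 5 members and did not pass (adjusted permutation p 0.18). Mitochondrially encoded genes had -0.29 over 11 members in the authors' deposited table (adjusted permutation p 0.0070) and -0.26 over 10 with names from the 2 h columns (0.011). Under the planned annotation they had -0.18 over 6 members (adjusted permutation p 0.37), or -0.08 with a mean over transcripts. None of the 11 passed singly by DESeq2, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Postsynaptic and adhesion proteins had 0.05 over 23 members (adjusted permutation p 0.0499), but 0.07 over 14 with names from the 2 h columns (0.26), 0.09 over 11 under the planned annotation (0.37) and -0.017 with a mean over transcripts.

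**Figure D1:**
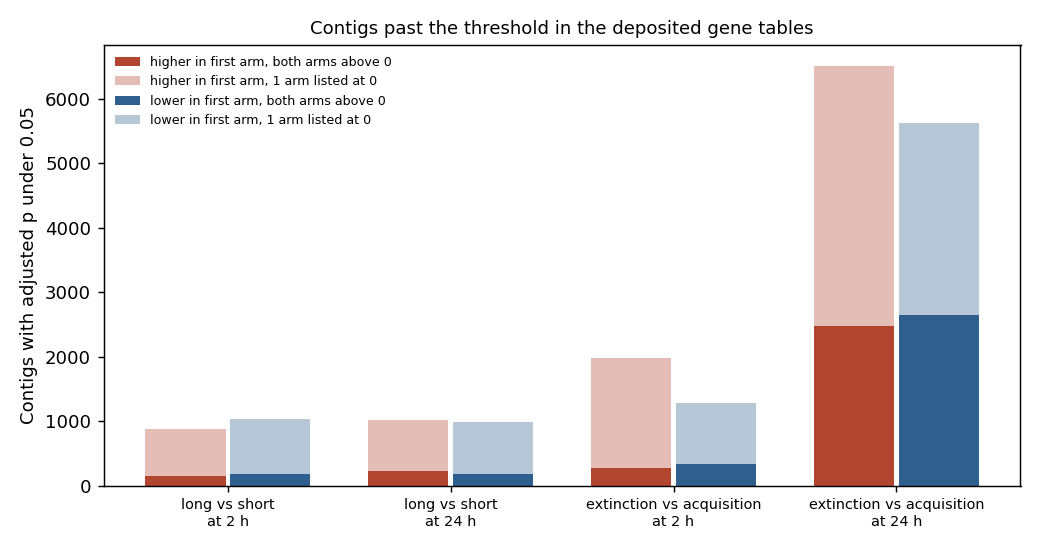
Contigs with an adjusted p under 0.05 in each of the 4 deposited gene tables (vertical axis, number of contigs), red for higher and blue for lower in the first-named arm, with contigs listed at 0 in 1 arm in the pale part of each bar. The comparison of the extinction and acquisition arms at 24 h holds 12144 contigs, against 1929, 2000 and 3261 in the others.

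The next pair of tables set an arm headed extinction against an arm headed acquisition, over the short-trained libraries and those of the earlier experiment, per the labels. The acquisition arm's means correlated with those of the short-trained arm at r = 1.00 across 120123 contigs at 2 h and across 118019 at 24 h. The extinction arm's did so at 0.70 and 0.65, and the long-trained arm's at 0.74 and 0.76, all on the log2 scale. The 2 arms came from separate experiments, so the experiment and the training cannot be told apart in any value of this pair. These tables were normalized separately from those of long and short training. At 2 h, the RNA-binding protein CIRBP, named for its induction by cold, was higher in the extinction arm at 1898 against 1307 in the authors' deposited table (contig TRINITY_DN374460_c0_g1, log2 fold change 0.54, DESeq2 adjusted p 0.0040). Stathmin, STM1A, a regulator of microtubules, was at 7045 against 5049 in the authors' deposited table (log2 fold change 0.48, adjusted p 0.046). Ribosomal protein contigs of the authors' deposited table went both ways, RL14 at 5100 against 3635 (0.49) and RL8 at 3791 against 6880 (-0.86, adjusted p 1.2e-05). A single contig of the heat shock protein HSPA1A was lower at 95.2 against 208 in the authors' deposited table (log2 fold change -1.13, adjusted p 0.044). The list of heat shock and glucocorticoid genes had 0 of 6 members called under the planned annotation (2 adjusted over the list alone) and 0 of 15 under the wider names.

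Further contigs higher in the extinction arm at 2 h in the authors' deposited table were ELAV4, a neuronal RNA-binding protein (154 against 4.71, log2 fold change 5.03), the farnesyltransferase subunit FNTA (1051 against 555, 0.92), LAP2A of the nuclear lamina (364 against 117, 1.64), GAL3B (370.3 against 203, 0.87) and the copper chaperone COX17 (48.8 against 1.36, 5.20). Beta-globin HBB had a mean of 199 in the extinction arm and was listed at 0 in the acquisition arm of the authors' deposited table (adjusted p 0.018). ZG8 (44.2) and ZN610 (25.5) were likewise listed at 0 in the acquisition arm of the authors' deposited table. Lower contigs in the authors' deposited table included the cell cycle protein APC13 (177 against 582, log2 fold change -1.72, adjusted p 1.5e-11), P53 (47.7 against 194.7, -2.03), ankyrin-1 (42.3 against 130.3, -1.62), OTOSP (164 against 372, -1.18), MORN3 (7.59 against 75.9, -3.32) and NDUAD of respiratory complex I (1345 against 1866, -0.47). Listed at 0 in the extinction arm of the authors' deposited table were RBX2 (193 in the acquisition arm), LFG4 (132), PADC1 (89.0), a second MHC class I contig (87.3), ZN551 (50.6), FHR2 (48.5), the protocadherin PCDA3 (44.4) and ZG7 (42.6). Mitochondrial contigs of the authors' deposited table moved in opposite directions within 1 gene: 1 COX3 contig had 6506 and was listed at 0 in the acquisition arm, and another had 4.44 against 111638.

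At 2 h, 3261 of 147146 contigs passed in the authors' deposited table by DESeq2 (1979 higher and 1282 lower in the extinction arm), of which 611 had both arms above 0 (269 higher, 342 lower). None of the 15 lists tested in the authors' deposited table passed an adjusted permutation p of 0.05, and 4 had an unadjusted permutation p under 0.05. These 4 were neuropeptides (median -0.36 over 15 members, adjusted permutation p 0.079), microglia and leukocyte markers (-0.69 over 7, 0.096), cytosolic ribosomal proteins (0.01 over 41, 0.10) and immediate early genes (0.14 over 11, 0.11). At an E-value of 1e-20 or less, 5 lists passed: these 4, with medians of -0.38, -0.69, 0.02 and 0.14, and mitochondrially encoded genes with -0.57, which had 0.14 with a mean over transcripts. With the wider names, which depend in part on p, microglia and leukocyte markers had -0.69 over 11 members (adjusted permutation p 0.0020) and neuropeptides -0.28 over 21 (0.045), with 0 members called by DESeq2 in either list and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 0 and 4 members. Ribosomal proteins then had 0.02 over 72 members in the authors' deposited table (adjusted permutation p 0.013; 2 higher, 1 lower, 3 adjusted over the list alone), but -0.06 with a mean over transcripts. Immediate early genes reversed to -0.049 over 19 members (adjusted permutation p 0.89). With names added only from the 24 h columns, microglia and leukocyte markers had -0.69 over 11 members (adjusted permutation p 0.0060), neuropeptides -0.30 over 20 (0.026) and ribosomal proteins 0.03 over 66 (0.0070). With random contigs matched on the tables that list them, neuropeptides did not pass (adjusted permutation p 0.072).

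At 24 h the extinction and acquisition arms differed most in number of calls. Some contigs of myelin and glia were called lower in the extinction arm, 4 of 11 myelin and 3 of 6 astroglial list members under the wider names. With names only from the 2 h columns neither list passed (adjusted permutation p 0.29 and 0.072). The contigs called lower were as follows. Claudin-11, a tight junction protein of myelin, had 92.7 against 323 in the authors' deposited table (contig TRINITY_DN393545_c8_g1, log2 fold change -1.80, DESeq2 adjusted p 1.8e-20), and the myelin enzyme CNP 267 against 607 (-1.18, adjusted p 3.7e-07). Myelin basic protein had 4617 against 9144 in the authors' deposited table (-0.99, adjusted p 0.0047), and UGT8, which makes myelin galactolipids, had 70.3 against 173 (-1.30, adjusted p 7.0e-05). Proteolipid protein, the main protein of central myelin, had 2746 against 6308 in the authors' deposited table (-1.20, adjusted p 1.1e-10). Glutamine synthetase, which glia use to recycle glutamate, had 9067 against 13668 in the authors' deposited table (-0.59, adjusted p 2.1e-05), and the glial glutamate transporter SLC1A3 had 3920 against 6119 (-0.64, adjusted p 4.7e-04).

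Neuropeptide contigs moved in both directions at 24 h in the authors' deposited table. The appetite peptide AGRP had 324 in the extinction arm against 23.1 in the authors' deposited table (log2 fold change 3.80, adjusted p 3.0e-04), and vasotocin, the amphibian homologue of vasopressin, had 2015 against 4457 (-1.14, adjusted p 7.9e-07). CARTPT (912 against 615, 0.57), VGF (1753 against 1272, 0.46) and ADCYAP1 (1641 against 1344, 0.29) were higher in the authors' deposited table, and secretogranin-1, SCG1, was lower (3544 against 4896, -0.47). Of 20 neuropeptides under the wider names, 4 rose and 2 fell in the authors' deposited table, or 8 adjusted over the list alone. Among kinases and phosphatases of calcium signalling, the calcineurin subunit PPP3CA fell by 0.59 on the log2 scale in the authors' deposited table (1063 against 1601, adjusted p 1.0e-14). The CAMK2G contigs fell by 0.56, 0.50 and 0.32, and CAMK2A by 0.47, whereas CAMK2D rose by 0.47 (824 against 596) and a CAMK2B contig of low mean by 4.05 (35.4 against 2.15), in the authors' deposited table. Their list of neurotrophin, CREB and kinase genes did not pass, with 1 of 28 members higher, 3 lower and a median of -0.09 under the wider names (adjusted permutation p 0.96). At synapses, complexin-1 (2710 against 3907, -0.53), VAMP2 (6138 against 7795, -0.34) and syntaxin-1A (794 against 985, -0.31) were lower in the authors' deposited table. The presynaptic list went both ways under the wider names, with 1 of 22 members higher, 3 lower and a median of -0.04 (adjusted permutation p 0.59). A contig of the receptor subunit GRIN1 had 368 against 549.95 (-0.58) and one of the calcium channel CACNA1B 168 against 80.3 (1.06) in the authors' deposited table. The glutamate receptor list did not pass. It had 1 of 5 members lower under the planned annotation, but 2 of 18 higher and 0 lower under the wider names, with a median of -0.15 (adjusted permutation p 0.84). Single contigs of FKBP5, a glucocorticoid target (173 against 374, -1.11), HSPA8 (249.5 against 418, -0.74) and HSPA1A (129.8 against 237, -0.87) were lower in the authors' deposited table. Their list of heat shock and glucocorticoid genes did not pass, with 1 of 15 members lower under the wider names and a median of -0.23 (adjusted permutation p 0.40).

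The muscle contigs of calsequestrin-1 (2.11 against 289, log2 fold change -7.09, adjusted p 7.1e-22) and troponin C (7.08 against 59.3, -3.06, adjusted p 0.049) were lower in the extinction arm at 24 h in the authors' deposited table. The muscle list did not pass, with 1 of 5 members lower and a median of -0.45 (adjusted permutation p 0.44), and skeletal actin had an adjusted p of 0.91 in the authors' deposited table. Several contigs were listed at 0 in the acquisition arm of the authors' deposited table, among them SELW (1079 in the extinction arm), CLIC6 of the choroid plexus (199.9), FHR2 (156), IF4E (133), DRB (92.4), ABCA3 (85.2) and RT14 (74.7). In the extinction arm, the authors' deposited table listed at 0 the tubulin TBA (2235 in the acquisition arm), LFG4 (379), the scaffold DLG2 (254), an immunoglobulin KV315 (88.5), ACE (85.2), ZO84 (69.9), ZN623 (63.9) and a DRC8 contig (58.8). Another DRC8 contig of the same Trinity component had 161 against 159 and did not pass. The FHR2 contig listed at 0 in the extinction arm at 2 h was also a different one, with 12.9 against 15.5 at 24 h. A COX2 contig had 100815 and was listed at 0 in the acquisition arm of the authors' deposited table, and a COX3 contig had 4.62 against 212515 while another had 9239 and was listed at 0 in the acquisition arm. A myelin contig, MAG, was listed at 0 in the extinction arm against 826 in the authors' deposited table, although at 2 h the same contig had 223 there and was listed at 0 in the acquisition arm. Another MAG contig, the one in the myelin list, had 745 against 921 at 24 h and did not pass (-0.31, DESeq2 adjusted p 0.33).

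In all, 12144 of 142142 contigs passed at 24 h in the authors' deposited table by DESeq2, 6516 higher and 5628 lower in the extinction arm, and 5141 of these had both arms above 0 (2485 higher, 2656 lower). Contigs with a protein hit leaned lower in the authors' deposited table: with both arms above 0, 75 were called higher and 283 lower, and their median log2 fold change was -0.13. None of 16 lists passed under the planned annotation, and 4 had an unadjusted permutation p under 0.05. With the wider names, the oligodendrocyte and myelin list had a median of -0.50 over 11 members in the authors' deposited table (adjusted permutation p 0.026), with 4 members lower, 7 not past the threshold and 5 adjusted over the list alone. These names depend in part on p at 24 h, and with names only from the 2 h columns the list had -0.38 over 5 members, 1 lower, and did not pass (adjusted permutation p 0.29). Astroglia and radial glia had -0.59 over 6 members (adjusted permutation p 0.024), with 3 lower and 5 adjusted over the list alone, but did not pass with names from the 2 h columns (-0.64 over 5, adjusted permutation p 0.072). Microglia and leukocyte markers had -0.92 over 12 members of the authors' deposited table (adjusted permutation p 0.013), with 0 called by DESeq2, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05. Immediate early genes had 0.19 over 19 members (adjusted permutation p 0.024), of which RGS2 fell (510.3 against 911, log2 fold change -0.84, 1 adjusted over the list alone) in the authors' deposited table. These 2 lists also passed with names from the 2 h columns (-0.92 over 10 and 0.29 over 12, adjusted permutation p 0.012 and 0.025). With random contigs matched on the listing tables, all 4 passed (adjusted permutation p 0.029, 0.027, 0.0084 and 0.029).

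**Figure D2:**
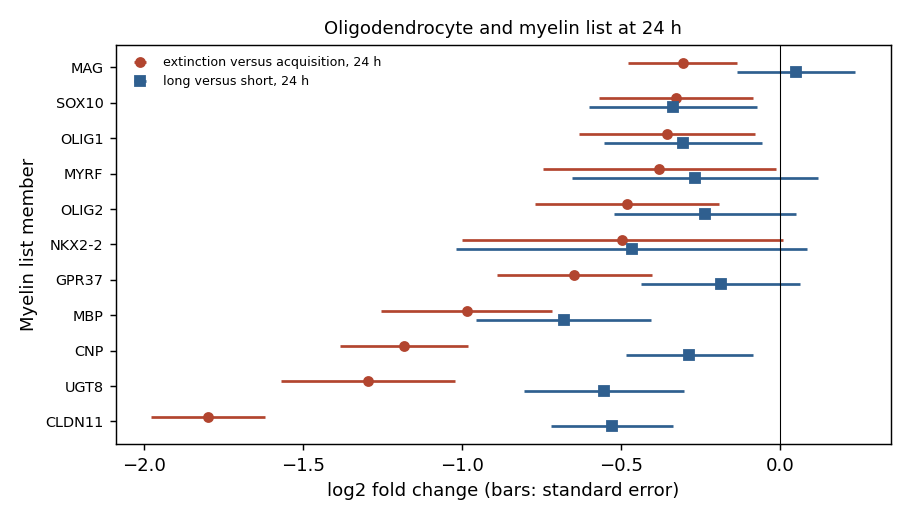
Log2 fold changes (horizontal axis; bars, 1 standard error, for the extinction and acquisition arms derived from the fold change and its p) of 11 oligodendrocyte and myelin genes at 24 h, red circles for the extinction against the acquisition arm and blue squares for long against short training. Claudin-11 lies at -1.80 and -0.53, and all 11 genes lie below 0 in red, 10 of 11 in blue; most were named from isoform tables that list only isoforms with an adjusted p up to about 0.25.

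Immediate early genes, which neurons induce with activity, were followed in every comparison whatever their result. FOS, EGR1 and ARC had no adjusted p under 0.05 by DESeq2 in any of the 4 gene tables, while NPAS4 and BDNF had no annotated contig here. FOS had 85.2 after long and 91.2 after short training at 2 h in the authors' deposited table (log2 fold change -0.10 with SE 0.41), and 17.7 against 17.6 at 24 h (0.01 with SE 0.86). EGR1 had 503 against 514 at 2 h and 224 against 191 at 24 h in the authors' deposited table (log2 fold changes -0.03 and 0.24). In the extinction arm FOS had 125 against 88.9 at 2 h and 35.4 against 17.8 at 24 h in the authors' deposited table (log2 fold changes 0.49 and 1.01, adjusted p 1.0 and 0.43). ARC there had 319 against 227 and 154 against 93.3 in the authors' deposited table (0.49 and 0.73), and EGR1 645 against 500.2 and 344 against 193 (0.37 and 0.84, the latter with adjusted p 0.081). Among isoforms of the extinction arm at 24 h, the authors' deposited table had EGR1 higher by 0.84 (adjusted p 0.042), NR4A1 by 1.49, NR4A3 by 1.56, IER2 by 0.57, JUN by 6.17, BTG2 by 7.20 and PER1 by 0.92 and 11.4. Isoforms of RGS2 were lower at -0.45 and -1.58 in the authors' deposited table, and at 2 h an isoform of JUN was higher by 6.99. At gene level at 24 h, the same contigs of NR4A1, NR4A3, JUN and PER1 had 0.83, 0.34, 0.15 and 0.60 in the authors' deposited table. Those of IER2 and BTG2 went the other way, each at -0.14. None of these passed at gene level (DESeq2 adjusted p 0.11 to 0.92), and the JUN contig had 0.20 at 2 h.

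**Figure D3:**
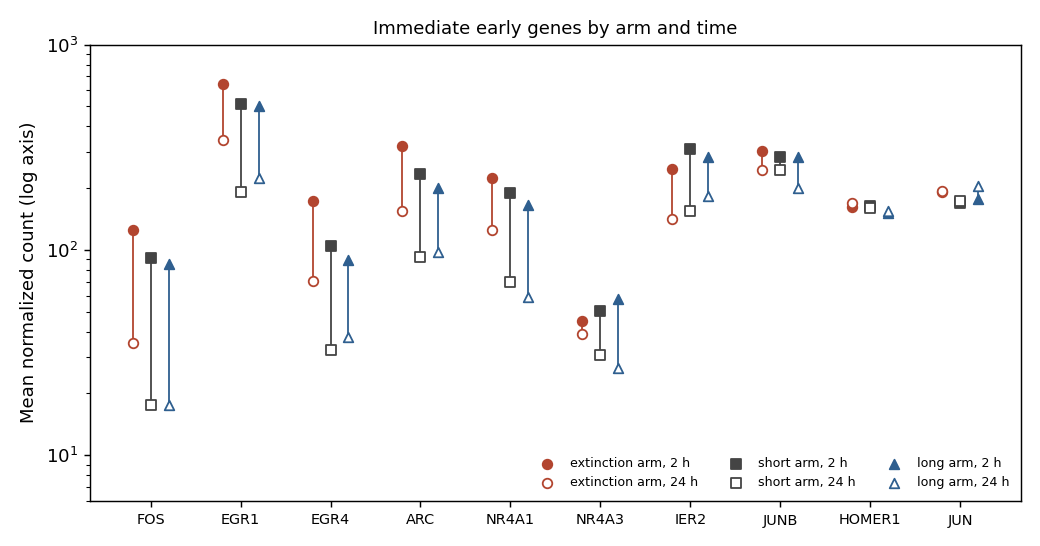
Mean normalized counts (vertical log axis) of 10 of the 19 immediate early genes of the list in the extinction, short-trained and long-trained arms, filled symbols at 2 h and open symbols at 24 h, from tables normalized separately for each time and each comparison. The genes shown include most of the large falls. Of all 19, 14, 17 and 14 were lower at 24 h in these arms. FOS lies at 125, 91.2 and 85.2 at 2 h and at 35.4, 17.6 and 17.7 at 24 h.

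The same training contrast was then compared between the 2 times, which share no library. For long against short training, the effect at 24 h differed from that at 2 h in 496 of 108692 contigs of the authors' deposited tables at an adjusted p under 0.05 (246 more positive at 24 h, 250 more negative), and 89 of these had all arms above 0. The gamma protocadherin PCDGG went from 0.65 at 2 h to -1.02 at 24 h in the authors' deposited tables, a difference of -1.67 (SE 0.40, adjusted p 0.011). WIPI4 went from 0.75 to -1.46 (difference -2.22, adjusted p 0.035), and ITF2 from -4.49 to 3.09 (difference 7.57, adjusted p 0.0092), in the authors' deposited tables. For the extinction and acquisition arms, 452 of 110493 contigs differed in the authors' deposited tables (258 more positive and 194 more negative at 24 h), 48 of them with all arms above 0.

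Both comparisons share the short-trained arm. At 2 h, 249 contigs were called in both of the authors' deposited tables and 246 went the same way. There, 91 were shared among those higher against 1.45 for independent lists, and 155 among those lower against 11.2. At 24 h, 460 of 475 went the same way in the authors' deposited tables, with 183 shared against 9.52 for those higher and 277 against 47.3 for those lower. With all arms above 0, 15 of 16 at 2 h and 109 of 115 at 24 h went the same way in the authors' deposited tables. The expected counts take no account of the shared arm, for which no expected count was computed. Over contigs with all arms above 0, the log2 fold changes correlated at r = 0.35 at 2 h and 0.42 at 24 h, against 0.50 and 0.49 in simulations of unchanged arms with the same shared arm. The covariances were 0.30 and 0.38 against simulated 1.31 and 1.11. At a base mean of 50 or more they were 0.12 and 0.19 against simulated 0.30 and 0.26. The simulations drew noise from the standard errors and gave each arm an equal share of the variance. They exceeded the whole observed covariance, so their setting did not match the data. They cannot tell how much of the agreement the shared arm gives, and no values per library were held with which to divide that arm.

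Non-vertebrate best hits were examined because an assembly without a reference can hold transcripts of other organisms. At 24 h, 28.7% of annotated contigs called higher in the extinction arm of the authors' deposited table had such a hit (37 of 129), against 14.96% of contigs not called (Fisher's exact test, adjusted p 3.7e-04), and 6.52% of those called lower did (adjusted p 5.8e-05). After long training at 2 h, 32.3% of contigs called lower had one in the authors' deposited table (10 of 31, adjusted p 0.026). At an E-value of 1e-20 or less the shares became 5.66% and 0.415% for contigs higher and lower at 24 h in the extinction arm, neither past an unadjusted p of 0.05. The share became 0% for those lower at 2 h after long training, below that of contigs not called.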

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

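All tests of the technical explanations in this part were chosen after the result was seen, except those of alternative contigs, of the whole locus and of the separate experiment; the list tests on the difference between times were also chosen after.

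Differences between arms were unlike at 24 h and 2 h in 496 contigs for long against short training and in 452 for the extinction and acquisition arms, from the authors' deposited tables; in the latter, experiment and training cannot be told apart. Among annotated contigs with all arms above 0, a set widened after a narrower one gave none, the protocadherin PCDGG differed by -1.67, the transcription factor ITF2 by 7.57 and the autophagy protein WIPI4 by -2.22 on the log2 scale. Cytosolic ribosomal proteins lay higher after long training at 2 h and lower at 24 h, with a median difference of -0.35 over 42 members (adjusted permutation p 0.0060). Subunits of oxidative phosphorylation had a median difference of -0.29 over 49 members for long against short training (adjusted permutation p 0.043) and 0.072 for the extinction and acquisition arms (adjusted permutation p 0.013). Neuropeptides had a median difference of 0.46 over 14 members for the latter arms (adjusted permutation p 0.0015). With isoform-table names, which depend in part on p at each time, oxidative phosphorylation no longer passed for those arms (0.031 over 69 members, adjusted permutation p 0.12). Passing with those names were neuropeptides (0.42, adjusted permutation p 0.0020), immediate early genes (0.24, 0.0067), myelin (-0.41, 0.0067) and astroglia (-0.30, 0.035) for those arms. For long against short training, ribosomal proteins (-0.34, 0.0020), mitochondrially encoded genes (-0.45, 0.0030), myelin (-0.49, 0.0040) and oxidative phosphorylation (-0.24, 0.0495) passed.

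A signal in a table outside the main comparisons was that 8 isoforms of 7 immediate early genes had an adjusted p under 0.05 in the isoform column headed long against short training at 24 h, all lower, among them FOS at -2.36, ARC at -1.38 and EGR1 at -1.28. The gene table had FOS at 0.01, ARC at 0.08 and EGR1 at 0.24 for that comparison. From 2 h to 24 h after long training, their gene means changed by -2.27, -1.04 and -1.17. The isoforms of EGR4, JUNB and NR4A3 were at -1.35, -0.58 and -3.65, and those of NR4A1 at -1.50 and -1.76. The time changes of these 4 genes, in that order, were -1.25, -0.51, -1.11 and -1.48, and the headed comparison gave 0.21, -0.30, -0.20 and -0.23. Each of the 8 isoforms thus lay closer to the time change than to the headed comparison. In signs, 72.2% of 144 isoforms went with the gene means of long training at 24 h against long training at 2 h and 58.3% with those of the headed comparison. Where the 2 contrasts had opposite signs, 70.8% of 48 isoforms took the sign of the time contrast (95% interval 56.8 to 81.8, binomial test p 0.0055). The column correlated at r = 0.44 with the time contrast and at 0.28 with the headed comparison. In each other isoform column the headed comparison matched the most signs. The shares there were 76.1% and 77.4% for the extinction and acquisition arms at 2 h and 24 h, and 70.9% for long against short training at 2 h. The immediate early isoforms thus went with the time contrast, and these values argue against the heading for the isoforms compared. Whether the whole column holds the time contrast stays open, since isoforms are not independent. A shift among isoforms with level gene sums also stays open, since only 1 gene had more than 1 listed isoform, both lower; no biological explanation was tested.

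Most contigs that passed had 1 arm listed at 0: 83.3% and 78.9% for long against short training at 2 h and 24 h, and 81.3% and 57.7% for the extinction and acquisition arms. Replacement of alternative contigs of a locus by each other was tested only in components with 2 or more such calls (50, 39, 137 and 784). The share of these with calls in both directions was 28% at its lowest, under the shuffled median of 52.0%, and in no comparison above it. At its highest, in the extinction and acquisition arms at 24 h, the share was 47.7% (374 of 784), against a shuffled median of 55.4%. The shares argue against replacement between such calls as the general pattern within those components. They do not exclude replacement in the components that held both directions. For the other calls replacement stays open, since a replacing contig not itself called with 1 arm at 0, or in another component, was not counted. Low level stays open: the share of such calls with a mean of 50 or more was 4.55% and 3.23% for long against short training, but 16.2% and 12.5% for the other arms. Such calls had median means of 17.6, 17.6, 18.9 and 23.8 in the same order, against 103, 120, 175 and 124 for the other calls. A whole locus switched after training also stays open, with component sums differing by 1 or more on the log2 scale for 35.8% of such calls at most. Spread between libraries within an arm was not available to either test.

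Myelin contigs were lower in the extinction arm at 24 h, with a list median of -0.50 over 11 members, most named from isoform tables that depend on p. A lower class of contigs with a protein hit stays open: with names from the 2 h columns alone the list had -0.38 over 5 members and did not lie apart from other contigs with a hit (permutation p 0.103). An earlier form of this test with all those names gave 0.0049 and was replaced because its members were partly chosen for their change. With random contigs matched on the listing tables, the same 11 members had a permutation p of 0.0055. The median of all contigs with a hit or isoform-table name and both arms above 0 was -0.12. A high short-trained arm shared with the long and short comparison stays open: the list was lower there too, and the mean difference between the comparisons was -0.41 (2 SE range -0.66 to -0.16). That SE came from the standard errors of the 11 genes and treated the genes and the 2 comparisons as independent. Myelin genes may vary together and the comparisons share an arm, so the range does not measure spread between libraries. An earlier form of this test on the 5 called contigs gave -0.74 and was replaced because those were chosen for the pattern. The separate experiment cannot be told apart from the training, since the table holds just 1 group of the earlier experiment at 24 h. A biological explanation by training stays open beside it, untested.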

How the results depend on the processing

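Restriction to contigs with both or all arms above 0, the names from the isoform tables in 3 forms, and a mean of 50 or more for the correlation of fold changes were chosen after the data were seen; the other alternatives were planned. Across alternatives, 48 main values stayed within the same side or range, 42 counts moved, 2 results were weaker, 2 stronger and 6 reversed; of the other values 436 stayed the same, 27 were stronger, 10 weaker and 9 reversed. Renewed adjustment over all contigs with a p left 189 named genes the same and 2 weaker.

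Counts are given for long against short training at 2 h and 24 h, then for the extinction and acquisition arms at 2 h and 24 h. At an adjusted p under 0.001 there were 826, 841, 796 and 6116 contigs, and 1792 at an adjusted p under 0.01 for the extinction and acquisition arms at 2 h. With a base mean of 50 or more there were 344, 404, 965 and 4877, with a Swiss-Prot hit 47, 44, 82 and 451, among isoforms in the shorter tables, 498, 484, 1408 and 7525, and with both arms above 0, 323, 423, 611 and 5141. These settings test fewer contigs or ask more of them by construction. The 484 isoforms come from the column that may hold long training at 24 h against long training at 2 h, as set out above. For the difference between times, 103 (base mean of 50 or more in both), 44 (all arms above 0) and 254 (adjusted p under 0.01) passed for long against short training, and 133, 11 and 214 for the other arms. The restricted sets were adjusted again within themselves, which is why 44 and 11 lie below the 89 and 48 of the full set's calls that had all arms above 0. Calls in common in the same direction numbered 15 at 2 h and 109 at 24 h with all arms above 0.

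For the fixed lists, the number past an adjusted permutation p of 0.05 for long against short training at 24 h became 0 with a mean over transcripts, 0 with the Wald statistic, 4 with isoform-table names, 4 with random contigs matched on the listing tables and 2 with names from the other time alone. For the extinction and acquisition arms it became 5 at 2 h and 3 at 24 h at an E-value of 1e-20 or less, 3 and 4 with isoform-table names, 2 and 4 with that matching, and 3 and 2 with names from the other time alone. With a mean over transcripts, postsynaptic and adhesion proteins reversed to -0.017 for long against short training at 24 h, and at 2 h ribosomal proteins reversed to -0.063 and mitochondrially encoded genes to 0.14 for the other arms. With isoform-table names, immediate early genes reversed to -0.049 at 2 h and oxidative phosphorylation to -0.0087 at 24 h for those arms, or to -0.049 and -0.0021 with names from the other time alone. The cause was not tested.

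Non-vertebrate shares at an E-value of 1e-20 or less fell to 0, 0, 0 and 0% for contigs higher and lower at 2 h and at 24 h after long training, to 0% and 4% for those higher and lower in the extinction arm at 2 h, and to 5.66% and 0.415% at 24 h. With a base mean of 10 or more they were 33.3% for contigs higher after long training at 24 h and 27.0% for those higher in the extinction arm at 2 h, both then under an unadjusted p of 0.05. The cause was not tested.

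No paired analysis was possible because the deposited tables hold no values per library. For the same reason TMM against DESeq2 size factors, a filter on low counts, DESeq2 against edgeR, a fit of 2 groups alone, the replicate block, the pseudocount, leave-one-out and other splits of the libraries were not run, and what depth limits is unknown.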

Other observations

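The tests across time in this part were chosen after the data were seen, and each level below comes from tables normalized separately for each time. The lists include isoform-table names, which depend in part on the adjusted p of isoforms in the comparisons. Immediate early genes were lower at 24 h than at 2 h in each arm by their means. FOS, a transcription factor induced by neuronal activity, went from 125 to 35.4 in the extinction arm, from 91.2 to 17.6 after short training and from 85.2 to 17.7 after long training. EGR1 went from 645 to 344, from 514 to 191 and from 503 to 224, and ARC, a synaptic plasticity protein, from 319 to 154, from 234 to 92.5 and from 200.5 to 97.6. Of 19 immediate early genes, 14, 17 and 14 were lower at 24 h, with median log2 ratios of -0.20, -0.39 and -0.51 (permutation p 1e-04 in each arm, the smallest possible).

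The median log2 ratio of 24 h over 2 h over all contigs compared was 0.13 in the extinction arm, 0.12 after short training and 0.03 after long training, and the ratios below include it. Myelin genes went apart between the arms over time, with median log2 ratios of 0.31 after short training, -0.21 after long training and -0.16 in the extinction arm (adjusted permutation p 0.042, 0.0033 and 0.016). Cytosolic ribosomal proteins had 0.27 after short training, 0.27 in the extinction arm and -0.08 after long training, where 62 of 69 were lower at 24 h (adjusted permutation p 6.7e-04, 0.039 and 0.0010). Less the median of all, these were 0.14, 0.14 and -0.11. Neuropeptides had 0.42 in the extinction arm, 0.08 after short training and -0.10 after long training (adjusted permutation p 0.0033, 0.31 and 0.013). Mitochondrially encoded genes had 0.50 after short training (0.38 less the median of all, adjusted permutation p 6.7e-04), 0.38 in the extinction arm (0.25, adjusted permutation p 0.029) and 0.04 after long training (0.01, adjusted permutation p 0.74). No Gene Ontology term passed an adjusted p of 0.05 by Fisher's exact test in any of 8 sets of calls, where 7 to 74 terms had an unadjusted p under 0.05. The sets of calls higher and lower held 4 and 2 proteins for long against short training at 2 h and 2 and 5 at 24 h. For the extinction and acquisition arms they held 5 and 14 at 2 h and 40 and 209 at 24 h. Sets of 2 to 5 proteins left little room for any term to pass.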
